A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

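RNA of S. cerevisiae BY4741 was measured on 4 Affymetrix Yeast Genome S98 arrays, 2 of control cells and 2 of cells kept for 15 min with quinine at 1 g/L, per the labels. Cells were taken in mid-exponential growth in MM4 medium and moved to fresh medium, and biotin-labelled cRNA was made from 8 ug of total RNA. The quinine was dissolved in ethanol, at 0.7% by volume in the medium, per the labels. Whether the control medium also held ethanol is not given in the sources used here. The groups and replicate numbers were taken from the labels, which do not say whether replicates were separate cultures. The p values therefore measure the spread between these samples, which may be technical.

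The deposited values are linear signal intensities of 1 value per probe set and array. The submitters' processing notes name MAS5, with no role and no version. The authors' table also holds, per probe set, each group's mean signal intensity, and its standard error and a fold change with lower and upper bounds, which are the authors' own scores, and the percent of a group's arrays with a Present call, deposited as a percent. The authors' means matched the means of the arrays here within a median of 0.079% in controls and 0.078% with quinine. Their fold was the ratio of those means, within 0.013. Their standard errors were above that of the 2 arrays alone in 95.9% and 97.7% of probe sets. The authors marked 777 probe sets, all with a lower bound of the fold of at least 1.2 in size. The 4 arrays had medians between 596 and 636, and how they were brought to a common scale is not given in the sources used here. The table held only probe sets called Present on at least 1 of the 4 arrays.

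Of 7519 probe sets, 5290 named 1 gene by an open reading frame that matched the reference gene table of assembly R64, from which symbols were taken. A further 480 named several genes, 364 had only gene text, 275 an open reading frame without a match, 1107 another feature and 3 names that disagreed. These were left out of the test. Of the 5290, those Present on at least 2 of the 4 arrays were kept, 5217 in all, and for genes with several probe sets the brightest was used. In 1 of 80 such genes the probe sets differed by over 1 log2 unit. This left 5129 genes. No genome build is named for the array features, and no coordinates are given. RNA quality, planned from the array's own control probe sets, was not analysed here.

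The signals were used as deposited, as log2 values with no pseudocount, and 3 values lay at a floor of 1. Quinine was compared with control in limma 3.58.1 under R 4.3.3 (lmFit, eBayes with a variance trend), with 2 residual degrees of freedom, a prior of 3.86 and Benjamini-Hochberg adjustment over all genes. A fold is 2 to the power of the log2 fold change, so it compares geometric means. Signals are given as mean ± SD of 2 arrays. The number of arrays limits the precision. A gene not called Present on either array of a group, as CAT8 and MAL31 in controls, has only a bound there, written as at least N-fold. On each array its level was taken as its own signal or the lowest signal among probe sets called Present on both arrays of that group, whichever was higher. Such a bound takes the dim signal as an upper limit and leaves out the error between arrays.

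Gene lists were 31, taken from general knowledge of yeast, of which 29 had at least 4 tested genes. Each was tested with camera (preset correlation 0.01), with adjustment over the 29 lists, and again with an estimated correlation and with fry, which asks whether a list's genes move one way and does not compare them with other genes. None of the 9 lists called with the preset correlation passed with the estimated one, where their adjusted p values lay between 0.724 and 0.845. With an estimated correlation camera also tests on the 2 residual degrees of freedom, so few lists could pass. For beta-oxidation, with an estimated correlation of -0.05, the unadjusted p by camera rose from 0.0117 to 0.113. Losing a call there is thus no measure of correlation alone. Members were also adjusted over the list alone. The direction of a list is the sign of its median.

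The rule for named genes was: the 10 called genes with the highest and the 10 with the lowest log2 fold change whose arrays did not overlap between groups, up to 4 called members of each list or, with none called, the 1 with the largest change as a value only, HIS3, LEU2, URA3 and MET17, which the strain lacks, and PDR5, SNQ2, TPO1, QDR1, QDR2, QDR3, HXT1, HXT2, HXT3, HXT4, TAT2 and SUC2. LEU2, URA3 and MET17 were not analysed here. Because 1 gene was called, other genes were named after their values were seen. These were the 10 highest and 10 lowest among genes with an unadjusted p under 0.05 in limma and no overlap of arrays between groups. Up to 4 members of each list that passed over the list alone were named too. A result of 1 further list member is not reported here. The groups, tests, lists, the rule and the alternatives were fixed before the data were examined, apart from the adjusted p limit of 0.1 the addition of features named by gene text only, and those tests of explanations that the closing section names as chosen later.

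Alternatives were quantile normalization, median centring, a pseudocount of 32, no filter, Present on all 4 arrays, no variance trend, the dimmest probe set, unique probe sets only, a replicate block, each array left out in turn (the lone array of a group then taken to vary like the other group), other limits for a call, the authors' table, and other list tests. The fit was tested on simulated data for the 5129 genes, drawn from the real means and fitted variances, with 200 changed genes: 52% of those changed by 1 log2 unit were called, 100% at 2, 98% at 3 and 100% at 4, along with 14 unchanged genes. With 1 list moved, camera called that 1 list. Genes were simulated independently of one another, while estimated correlations within the called lists reached 0.77, as in the respiratory chain. The simulation thus does not test camera's calls under such correlation. In the real data MPC3 and TMA10, at log2 fold changes of 3.16 and 4.22, were not called, so these shares may not hold.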

Results

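Transcript levels were measured across the genome of the haploid laboratory yeast strain BY4741 (Saccharomyces cerevisiae) after a short exposure to quinine, an alkaloid used against malaria. The data comprised 4 Affymetrix yeast arrays, each hybridised with labelled RNA of 1 sample. There were 2 arrays of control cells and 2 arrays of cells kept for 15 min with quinine at 1 g/L. The comparison of the 2 groups addressed the early transcriptional reaction of the cells to the drug. The median deposited signal was 621 and 626 on the control arrays and 636 and 596 on the quinine arrays, over 7519 probe sets. Within a group, the signals of a gene on the 2 arrays differed by a median of 0.21 on the log2 scale in controls and 0.20 with quinine.

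With quinine, genes for the use of carbon sources other than glucose were higher, and genes for making ribosomes were lower, as lists tested by camera with a preset correlation between genes. With an estimated correlation the lists of gluconeogenesis, other sugars and ribosome biogenesis each had an adjusted p of 0.724, and 1 gene passed over all genes. The clearest single gene was MAL33 (YBR297W), of the family of maltose activator genes. Whether it works as an activator in this strain was not tested. Its signal rose from 89.6 ± 23.5 (SD, n = 2) to 946 ± 158 (SD, n = 2), 10.7-fold. Its log2 fold change of 3.42 had a standard error of 0.24 and an adjusted p of 0.0489 in limma, the only adjusted p under 0.05 among 5129 genes. The call was close to the threshold: the adjusted p of MAL33 was 0.0725 after quantile normalization, 0.0545 after median centring, 0.0795 without a variance trend, and 0.176 or 0.237 without either quinine array.

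Genes of gluconeogenesis, the glyoxylate cycle and non-fermentable carbon use rose as a group: all 23 tested members were higher with quinine, with a median log2 fold change of 0.85. In 10 of the 23, the change passed the test adjusted over the list alone, and 0 passed over all genes. CAT8, the transcriptional activator of gluconeogenic genes, had a signal of 47.3 ± 13.2 (SD, n = 2) in controls, where it was not called Present on either array, and 360 ± 29.4 (SD, n = 2) with quinine. With the control signal of CAT8 taken as an upper limit, it was at least 7.74-fold higher, and at least 6.33-fold without control replicate 2, the lowest value when 1 array was left out. ALD4, a mitochondrial aldehyde dehydrogenase, was at 933 ± 507 in controls and 5567 ± 575 with quinine (SD, n = 2 each), a fold of 6.44. The mitochondrial glycerol 3-phosphate dehydrogenase gene GUT2 had a fold of 4.57 and the carnitine carrier gene CRC1 one of 5.99. The genes of the gluconeogenic enzymes themselves, FBP1 and PCK1, moved less, with folds of 1.15 and 1.53. Both had arrays that overlapped between groups, and neither passed over the list alone. By camera the list had an adjusted p of 9.0e-13 with the preset correlation between genes, and an adjusted p of 0.724 with an estimated correlation.

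Genes for other sugars rose as well. Of the 12 tested genes for sucrose, maltose and galactose use, 11 were higher, with a median log2 fold change of 0.58, and 6 passed the test adjusted over the list alone, while 1 (MAL33) passed over all genes. The maltose permease genes MAL31 and MAL11 were among the 6, MAL11 with a fold of 2.83. MAL31 was not called Present on either control array and, with its control signal taken as an upper limit, was at least 3.12-fold higher, and at least 2.66-fold without control replicate 2, the lowest value when 1 array was left out. GAL4, the activator of the galactose genes, had a fold of 2.22. MAL11 and GAL4 were each called Present on 1 of the 2 control arrays. SUC2, which encodes invertase, had a signal of 675 ± 17.6 (SD, n = 2) in controls and 1121 ± 103 (SD, n = 2) with quinine, and its adjusted p over all genes was 0.123 in limma. The adjusted p of this list was 3.8e-07 by camera and 0.724 with an estimated correlation.

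Hexose transporter and glucose sensing genes were higher in 12 of 15 tested members, with a median log2 fold change of 0.64, and the list rose with an adjusted p of 3.2e-04 by camera (adjusted p of 0.724 with an estimated correlation). Adjusted over the list alone, 4 members passed and 0 did over all genes. These were MTH1, a regulator in glucose sensing, with a fold of 10.1, the glucose sensor gene SNF3 with a fold of 3.48, and the transporter genes HXT4 and HXT2 with folds of 3.26 and 2.17. HXT1 and HXT3, which encode low-affinity glucose transporters, had log2 fold changes of 0.64 ± 0.36 and 0.63 ± 0.22 (SE) and passed neither test. MTH1 was called Present on 1 of the 2 control arrays, where its signals were 128 and 41.7, so its fold rests in part on a signal not called above background. It was 17.7 without control replicate 1 and 5.73 without control replicate 2. The list's median was 1.19 without control replicate 1, 0.28 without control replicate 2 and 1.06 without quinine replicate 2.

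Storage carbohydrate and respiratory genes moved in the same direction. In the trehalose and glycogen list, 17 of 19 tested genes were higher (median log2 fold change 0.50, adjusted p of 2.4e-07 by camera, adjusted p of 0.724 with an estimated correlation), and 5 passed the test adjusted over the list alone, with 0 over all genes. Among them, GLG1, which primes glycogen synthesis, had a fold of 3.38, the glycogen branching enzyme gene GLC3 3.12, the glycogen synthase gene GSY1 3.08 and the trehalase gene ATH1 2.16. Of 34 genes of the respiratory chain and ATP synthase, 33 were higher, by a median of 0.29 (adjusted p of 4.9e-07, adjusted p of 0.845 with an estimated correlation). The NADH dehydrogenase gene NDI1, with a fold of 3.39, was the 1 member that passed over the list alone, with 0 over all genes. The tricarboxylic acid cycle list rose with a median of 0.24 and 14 of 17 genes higher (adjusted p of 0.00169, adjusted p of 0.814 with an estimated correlation). Over this list alone, CIT3 (4.26-fold), SDH2 (2.44-fold) and SDH3 (1.66-fold) passed as higher, and 0 passed over all genes. Without control replicate 1, control replicate 2, quinine replicate 1 and quinine replicate 2 in turn, the medians were 0.84, 0.35, 0.39 and 0.79 for trehalose and glycogen, 0.46, 0.14, 0.17 and 0.43 for the respiratory chain, and 0.37, 0.23, 0.14 and 0.36 for the tricarboxylic acid cycle. Relative to the control mean, quinine replicate 2 had a median of 0.17 and control replicate 1 one of 0.15 for the respiratory chain, and medians of 0.14 and 0.13 for the tricarboxylic acid cycle, so for these 2 lists 1 quinine array lay about level with 1 control array.

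Ribosome biogenesis genes, whose products process ribosomal RNA and assemble ribosomal subunits, fell as a group. Of 65 tested genes 64 were lower, with a median log2 fold change of -0.69, and 46 passed the test adjusted over the list alone, with 0 over all genes. The signal of SSF1, a factor of the large subunit, was 423 ± 140 in controls and 140 ± 21.7 with quinine (SD, n = 2 each), a log2 fold change of -1.57. RRP14, UTP7 and DBP8 had log2 fold changes of -1.28, -1.27 and -1.23. The adjusted p of the list was 4.1e-23 by camera and 0.724 with an estimated correlation. The genes of the ribosomal proteins themselves did not pass: of 94 genes 66 were lower and 28 higher, the median was -0.04 and the adjusted p 0.528, with 0 genes past either test. Both quinine arrays lay below both control arrays in 20 of them and above in 4. By fry the list had an unadjusted p of 0.0414, pointing down, and an adjusted p of 0.232. Of 10000 random lists matched on mean signal, 0.08% had a lower median, so a small fall is not excluded. That draw treats genes as independent. Among the 94, RPL36B had the largest log2 fold change, -0.34 ± 0.17 (SE).

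**Figure D1:**
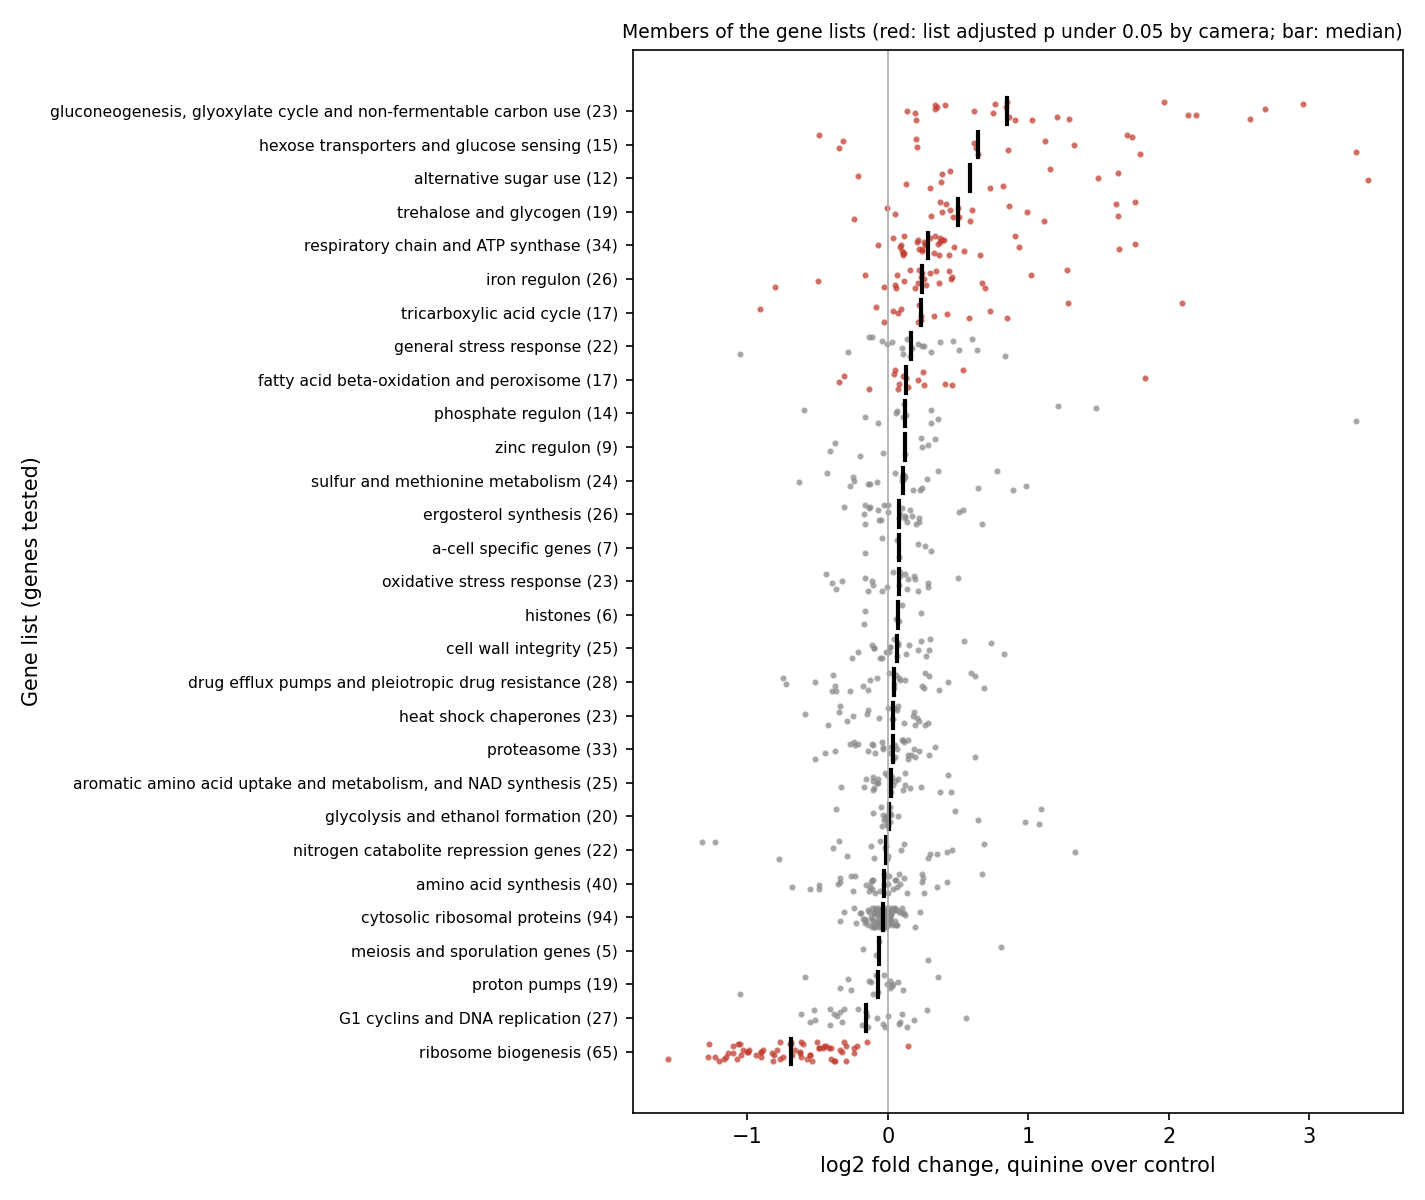
Log2 fold changes of quinine over control (x axis) for the tested members of 29 gene lists (y axis, number of tested genes in parentheses). Each point is a gene, black bars are list medians, and red marks the lists with an adjusted p under 0.05 by camera with the preset correlation. Ribosome biogenesis lies lowest, at a median of -0.69, and gluconeogenesis highest, at 0.85.

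The iron regulon and the list of fatty acid beta-oxidation and the peroxisome also passed by camera. In the iron regulon, 22 of 26 genes were higher (median 0.24, adjusted p of 0.00129, adjusted p of 0.814 with an estimated correlation), though 0 genes passed over the list alone or over all genes, and TIS11, which promotes decay of messenger RNAs when iron is scarce, had the largest value, 457 ± 312 in controls and 977 ± 153 with quinine (SD, n = 2 each). Its fold was 4.10 without control replicate 1 and 1.43 without control replicate 2. Beta-oxidation genes were higher in 14 of 17 (median 0.13, adjusted p of 0.0376, adjusted p of 0.724 with an estimated correlation), where the acyl-CoA synthetase gene FAA2 had a fold of 3.56 and was the 1 gene past the test over the list alone, with 0 over all genes. This last call was lost without control replicate 1 (adjusted p of 0.113), without quinine replicate 2 (0.150) and with a filter for Present on all 4 arrays (0.0764). By fry it was the 1 list of 29 with an adjusted p under 0.05, at 0.0229.

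Drug efflux and drug resistance genes did not pass as a list: 16 of 28 were higher, the median was 0.04, the mean -0.004 and the adjusted p by camera, with the test pointing up, 0.499, with 0 genes past either test. The log2 fold changes of the pump genes PDR5 and SNQ2 were 0.24 ± 0.17 and 0.29 ± 0.17 (SE), those of the transporter genes QDR1, QDR2 and QDR3 were 0.09 ± 0.20, 0.25 ± 0.21 and -0.39 ± 0.17, and that of the polyamine transporter gene TPO1 was -0.37 ± 0.18. QDR1 was at -0.01 without control replicate 2 and at -0.09 without quinine replicate 1. The list's largest value, that of TPO2, was -0.75 ± 1.39 (SE). It was 1.31 without control replicate 1, 0.43 without quinine replicate 2 and -2.80 without control replicate 2, since its signal was 3320 and 192 on the control arrays and 1078 and 211 on the quinine arrays. The median of the list was -0.08 without quinine replicate 1. TAT2, a tryptophan and tyrosine permease gene, had a signal of 2251 ± 48.3 in controls and 3036 ± 98.1 with quinine (SD, n = 2 each), with an adjusted p of 0.206 in limma, and its list of aromatic amino acid and NAD genes had a median of 0.03 over 25 genes (adjusted p of 0.446), with TRP4 at 0.45.

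Stress-related lists did not pass either. General stress genes had a median of 0.17 over 22 genes (adjusted p of 0.188 by camera). The list was drawn up as targets of the activators Msn2 and Msn4, but it also held regulator genes, MSN2, MSN4, YAK1 and RIM15. The membrane heat shock gene HSP30 had the largest log2 fold change, -1.05 ± 0.84 (SE). It was 0.25 without control replicate 1 and -2.35 without control replicate 2. The stress list hinged on single arrays: its median was 0.64 without control replicate 1 and 0.65 without quinine replicate 2 (adjusted p of 0.000131 and 0.00162), but -0.21 without control replicate 2 and -0.28 without quinine replicate 1. Heat shock chaperone genes had a median of 0.04 over 23 genes against a mean of -0.03, with the test pointing up (adjusted p of 0.778), with SIS1 at -0.59, oxidative stress genes 0.08 over 23 (0.588), with AAD4 at 0.50, and proteasome genes 0.04 over 33 (0.582), with PRE8 at 0.62. Cell wall integrity genes had a median of 0.06 over 25 genes (0.0962), with PRM5 at 0.83, and this list passed without control replicate 1 and without quinine replicate 2 (adjusted p of 0.00181 and 0.00477).

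Among the lists for nutrients, phosphate genes had a median of 0.12 over 14 genes and an adjusted p of 0.0962 by camera, and 1 of them passed over the list alone: the sodium phosphate cotransporter gene PHO89, at 1014 ± 758 in controls and 8686 ± 881 with quinine (SD, n = 2 each), a fold of 10.1. The fold of PHO89 was 18.1 without control replicate 1 and 5.59 without control replicate 2. Without control replicate 1 the phosphate list passed, with a median of 0.43 and an adjusted p of 0.000381. Sulfur and methionine genes had a median of 0.11 over 24 (0.122), and MUP3, SUL1, MMP1 and SAM3, all genes of transporters, passed over the list alone with folds of 1.97, 1.85, 1.71 and 1.56, SUL1 being called Present on 1 of the 2 control arrays. Nitrogen catabolite repression genes had a median of -0.01 over 22 with the test pointing up (0.900), and over the list alone GDH2 passed with a fold of 2.52, and the ammonium permease gene MEP3 and the amino acid permease gene AGP1 with log2 fold changes of -1.32 and -0.78. In these 3 lists 0 genes passed over all genes. Medians and adjusted p values were -0.03 and 0.816 for 40 amino acid synthesis genes, with ARG3 at -0.68, 0.12 and 0.601 for 9 zinc genes, with IZH2 at -0.41, and 0.005 and 0.147 for 20 glycolysis genes, with the glucokinase gene GLK1 at 1.09.

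The other lists gave no call. Ergosterol genes had a median of 0.08 over 26 genes (adjusted p of 0.315), with ECM22 at 0.67, and proton pump genes -0.07 over 19 (0.550). Genes of G1 cyclins and replication had a median of -0.15 over 27 (0.315), with CDC45 at -0.62. Without control replicate 1, the ergosterol and G1 lists had medians of 0.24 and -0.31. The G1 median was -0.21 without quinine replicate 2, but -0.07 without control replicate 2 and -0.08 without quinine replicate 1. Histone genes had a median of 0.07 over 6 (0.550), with HTB2 at 0.24. The a-cell genes, which this mating type expresses, had a median of 0.08 over 7 (0.405), with BAR1 at 0.31. Without quinine replicate 1 this median and BAR1 were both at 0.005, and without quinine replicate 2 they were at 0.22 and 0.61. The a-cell median was 0.19 without control replicate 1. Proton pump and histone medians ranged from -0.13 to -0.01 and from 0.02 to 0.07 when 1 array was left out, and that of sulfur and methionine genes from 0.03 to 0.13. Meiosis genes had a median of -0.06 over 5 and a mean of 0.16 with the test pointing up (0.582), with IME2 at 0.81. Only 3 alpha-cell genes were measured, too few for the list test, with a median of 0.10 and SAG1 at 0.22. Of the genes that the strain lacks, HIS3 was the 1 measured, with signals of 3901 and 4764 in controls and 3506 and 3277 with quinine. The deletion of HIS3 in this strain is known to be partial, so its probe set can lie outside the deleted part and checks nothing about the samples.

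The 10 highest and 10 lowest genes by log2 fold change were picked after the values were seen. Only genes with an unadjusted p under 0.05 in limma and no overlap of arrays between groups could be picked. The adjusted p values of the picked genes lay between 0.0489 and 0.0952 in limma. Besides the genes above, the highest were TMA10, from 107 ± 112 to 1362 ± 307 (SD, n = 2 each), the mitochondrial pyruvate carrier gene MPC3 with a fold of 8.92, PDH1 with 7.15 and RGI1 with 4.81. TMA10 was called Present on 1 of the 2 control arrays, where its signals were 187 and 27.9, so its fold, 7.20 without control replicate 2 and 48.1 without control replicate 1, rests in part on a signal not called above background. The fold of PDH1 was 11.3 without control replicate 1 and 4.53 without control replicate 2. Beyond SSF1 and MEP3, the lowest were MAK21, FAF1, SSF2, REX4, YOL014W, FAL1, RRT14 and RRP15, between -1.50 and -1.33. Of these, MAK21, FAF1, SSF2, FAL1 and RRP15 are known factors of ribosome assembly that were not on the ribosome biogenesis list. SSF2 was read by a probe set not counted as unique, so its value may also reflect related genes.

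**Figure D2:**
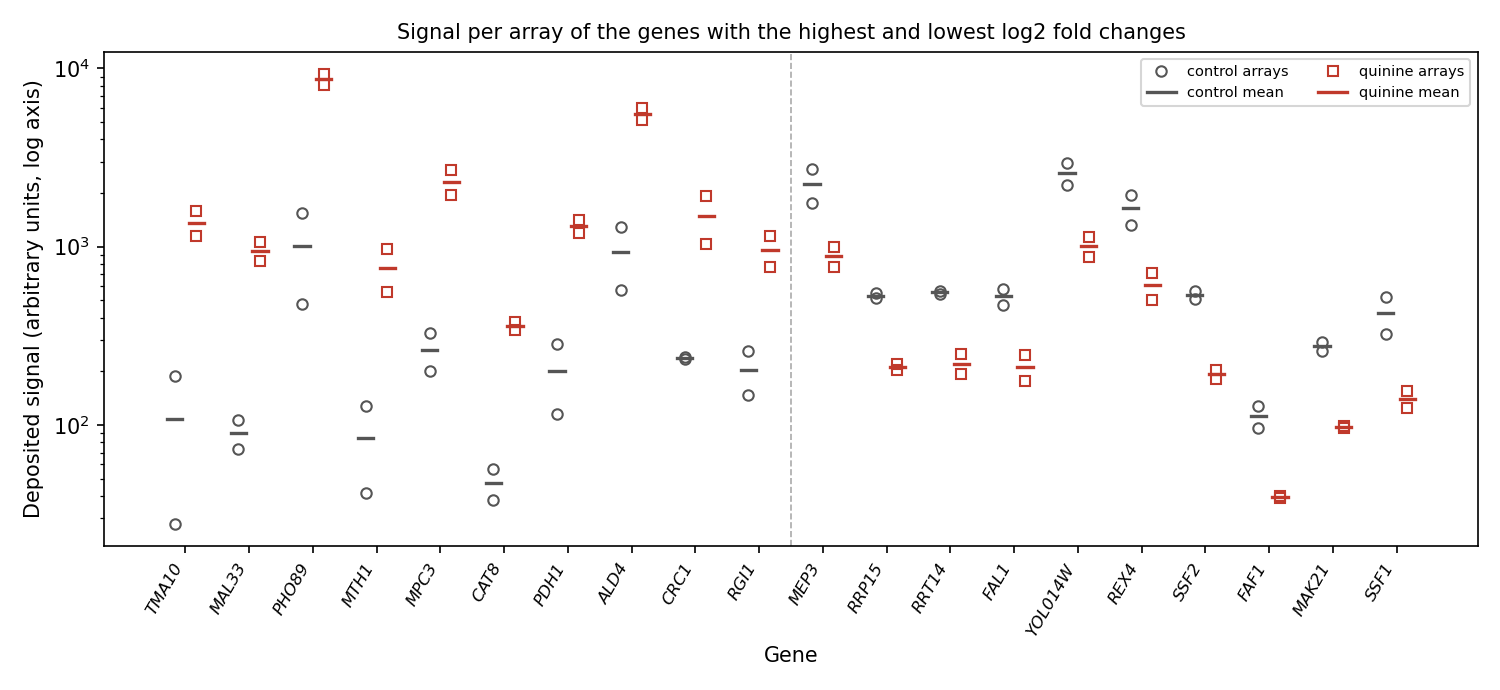
Deposited signal (y axis, arbitrary units, log axis) on each array for the 10 genes with the highest and the 10 with the lowest log2 fold changes (x axis, divided by the dashed line). Only genes with an unadjusted p under 0.05 in limma and no overlap of arrays between groups were ranked. Circles are control arrays, squares are quinine arrays and bars are the means of 2 arrays. For MAL33 the control arrays lie at 106 and 73.0 and the quinine arrays at 834 and 1058.

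Over all 5129 genes, limma called 1 gene higher and 0 lower at an adjusted p under 0.05, and 937 genes had an unadjusted p under 0.05, of which 323 were higher and 614 lower. At an adjusted p under 0.1, a limit chosen after the data were seen, there were 66 genes higher and 99 lower. In the authors' deposited table, 306 probe sets were marked as higher and 471 as lower, and all 165 genes with an adjusted p under 0.1 carried a mark. Both quinine arrays lay above both control arrays in 1014 genes and below them in 1528, together 49.6% of genes where chance gives 33.3%. With 2 arrays against 2, an exact permutation test of a single gene cannot go below a two-sided p of 0.333. Genes called over all genes ranged from 0 to 106 when 1 array was left out, with 106 without control replicate 1, 25 without control replicate 2 and 0 without quinine replicate 1 or without quinine replicate 2, where 644 and 511 genes had an unadjusted p under 0.05.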

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

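The test of general stress as an explanation, the split by brightness in controls and both tests of scaling between arrays were chosen after the results were seen. So were the question of a shared culture or day and the rule on intervals for both splits by brightness. The other tests were written down before.

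Outside the genes tested, 9 probe sets had both quinine arrays at least 2-fold above both control arrays and 2 had both at least 2-fold below, a signal in data that no comparison used. Of the probe sets shared by several genes, 1 for the maltose activator genes (assigned to YPR196W in one column and to MAL33 in another) went from 800 ± 91.2 in controls to 3251 ± 70.5 with quinine (SD, n = 2 each), a fold of 4.08. Another, shared by the sodium pump genes ENA1 and ENA2, went from 1654 ± 13.2 to 3940 ± 537, a fold of 2.37. The pair of probe sets shared by the high-affinity glucose transporter genes HXT6 and HXT7 had folds of 1.98 and 1.91. The highest fold among features with no gene name was 9.24, from 67.6 ± 43.1 to 574 ± 194.

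The first pattern is that genes on the lists of gluconeogenesis, other sugars, and hexose transporters and glucose sensing were higher with quinine. Low signals near background may inflate folds. Of 50 genes on the 3 sugar and gluconeogenesis lists, the 19 brighter than the median gene had a median log2 fold change of 0.64 (95% bootstrap interval over members 0.19 to 0.90). The 15 brighter in controls had one of 0.63 (0.14 to 0.90). The median of 0.64 passed the limit written down before against this explanation, which set no rule for the interval. By a rule on the interval added later, both intervals were too wide to settle it, so it was left open. A general stress response would move stress genes as much, but the gluconeogenesis median exceeded that of the stress list by 0.68 (95% bootstrap interval over members 0.33 to 1.09), and by 0.39 to 0.90 when 1 array was left out. The bootstrap intervals resample genes with the 4 arrays held fixed, as if genes moved independently, so they leave out the spread between arrays. The stress median alone ran from -0.28 to 0.65 when 1 array was left out. The difference thus holds for these 4 arrays only. Ethanol in the drug's medium stays open: 0 arrays are given ethanol without quinine in the labels, so it cannot be told apart from the drug. An effect of quinine on glucose use is a possible explanation that was not tested here.

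The second pattern is that ribosome biogenesis genes were lower while ribosomal protein genes were not called. A scale factor between arrays moves all genes alike, and the median log2 fold change over all genes was -0.025. This argues against it only for the list's fall relative to other genes. The close array medians, 596 to 636, may come from the scaling itself, so they argue neither way. A shift of all genes could thus be hidden. The ribosome biogenesis median was -0.68 after quantile normalization, but with arrays this close that step could change little. Saturation of bright probe sets might hide a fall of ribosomal protein genes: among 172 other genes of like brightness, only 1 had a log2 fold change as large as the ribosome biogenesis median and 0 were lower by that much, which leaves saturation open. A drug effect on ribosome assembly genes stays untested beyond the comparison itself.

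The third pattern is a difference between replicates 1 and 2, in both groups, seen in genes of the general stress list among others. The list's median was higher in replicate 1 by 0.74 (log2) in controls and by 0.79 with quinine, and 19 of its 22 genes were higher in replicate 1 in both groups. A scale factor moves all genes alike, so it would not set this list apart from other genes. The array medians, 621 and 626 in controls and 636 and 596 with quinine, may be close because of scaling. They argue neither way on a shift of all genes. The smaller of the differences was still 0.75 after quantile normalization, but with medians this close that step could change little. Of the 9 lists called with quinine, 7 differed the same way in both groups, such as hexose transporters (0.76 in controls, 0.42 with quinine), gluconeogenesis (0.36, 0.46), the respiratory chain (0.30, 0.19) and the tricarboxylic acid cycle (0.27, 0.21), but not other sugars (0.19, -0.01) or beta-oxidation (-0.08, 0.05). A culture or day shared by arrays of the same number could give this, but the labels name none, so it cannot be told apart from chance differences between samples, and no biological explanation was tested.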

How the results depend on the processing

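The adjusted p limit of 0.1 and the features named by gene text were chosen after seeing the data. Genes called (total, higher, lower) were 1, 1 and 0 in the main comparison. The totals were 0 after quantile normalization, after median centring, without a variance trend, with features named by gene text and at an adjusted p under 0.01, with 929 to 1070 genes at an unadjusted p under 0.05. They were 2 (2 higher) with a pseudocount of 32 and with unique probe sets only. At an adjusted p under 0.1 they were 165, 66 and 99. With no test, 51, 39 and 12 genes had both quinine arrays at least 2-fold beyond both control arrays, and 152, 82 and 70 were at least 2-fold changed in the authors' deposited table. Leaving out 1 array gave 0 to 106 in total, 0 to 89 higher and 0 to 17 lower. The cause of these shifts was not tested. Between 8 and 9 lists were called under the settings of scaling, filter and probe set, 9 to 13 without 1 array, 0 with an estimated correlation and 1 by fry. The beta-oxidation list was lost with Present on all 4 arrays and with gene text features (adjusted p of 0.0764 and 0.0520). The other 8 called lists kept their direction and call in every fit of camera with the preset correlation.

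The samples share only a replicate number. With the replicate block, 1458 genes were called (589 higher, 869 lower), including MAL33 and all 165 genes with an adjusted p under 0.1, on 1 residual degree of freedom. The lowest adjusted p of this limma fit was 1.31e-132, which 4 arrays cannot support, so its p values rest on the variance assumed from other genes. The 1458 calls are thus no evidence of as many changed genes. The phosphate list was then called and the beta-oxidation list was not (adjusted p of 3.4e-05 and 0.0876). As a check of pairing, differences between replicates 1 and 2 correlated at 0.62 between the groups, across genes, which are not independent replicates.

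These medians, all of lists not called in the main comparison, changed sign. Gcn4 targets and nitrogen catabolite repression were at 0.004 and 0.021 after median centring, and meiosis genes at 0.102 with Present on all 4 arrays. Leaving out 1 array gave -0.106 to 0.030 for Gcn4 targets, -0.218 to 0.132 for nitrogen, -0.109 to 0.213 for meiosis, -0.001 to 0.030 for glycolysis, -0.277 to 0.652 for general stress, -0.109 to 0.101 for heat shock, -0.094 to 0.238 for ergosterol, -0.062 to 0.205 for zinc, -0.057 to 0.426 for phosphate, -0.068 to 0.062 for oxidative stress, -0.147 to 0.157 for the proteasome, -0.078 to 0.188 for drug efflux, -0.062 to 0.071 for aromatic amino acids and -0.091 to 0.217 for the cell wall. Among genes it gave -2.35 to 0.25 for HSP30, -2.80 to 1.31 for TPO2 and -0.092 to 0.269 for QDR1. The cause was not tested. Dim probe sets limit folds: 3 values lay at the floor of 1.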

Other observations

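The general stress genes that differed most between replicates, chosen after their values were seen, did so in both groups. HSP26, a small heat shock protein gene, had signals of 1270 and 149 on control replicates 1 and 2, and 1330 and 200 on the quinine ones. HSP12, another small heat shock gene, was at 1730 and 425 in controls and at 2150 and 413 with quinine. YGP1, a cell wall glycoprotein gene, was at 5700 and 790 in controls and at 4780 and 1200 with quinine. The high-affinity phosphate transporter gene PHO84 also varied, at 4060 and 378 in controls and 4300 and 1910 with quinine. Across genes, which are not independent replicates, control replicate 1 correlated with quinine replicate 1 (r = 0.973) about as closely as with control replicate 2 (r = 0.972), while quinine replicate 2 correlated more closely with quinine replicate 1 (r = 0.982) than with control replicate 2 (r = 0.958).

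Other classes of array features moved little by median. The 367 probe sets of Ty elements and their long terminal repeats had a median log2 fold change of -0.07, the 82 of tRNAs -0.08, the 61 of small nuclear and nucleolar RNAs 0.02 and the 5 of ribosomal RNA 0.15, and 0 of these were 2-fold apart on all arrays in either direction.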
